A study of Mus musculus and Homo sapiens with 24 samples.

How the data were processed

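Polyadenylated RNA was sequenced from a pair of established skeletal myoblast lines during differentiation, the mouse line C2C12 and the human line LHCN-M2. Per the labels, messenger RNA was captured on poly-T beads, cDNA was primed with random hexamers, and a strand-marking option of the library kit is mentioned without a statement that it was used. There were 24 libraries in 6 groups of 4: C2C12 at days 0, 1 and 6, and LHCN-M2 at days 0, 1 and 12. All samples carry the genotype label control. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

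The deposited tables hold counts of reads per gene, 1 column per library, whole numbers with no normalization, in 56748 gene rows for C2C12 and 58735 for LHCN-M2. Per the submitters' processing notes, fastp, HISAT2 2.2.1, StringTie 2.2.3 and featureCounts 2.0.6 were used, and the genome builds mm10, GRCh38 and hg38 are named. The annotation release, the strand setting of the counting and any filter on reads are not given in the sources used here. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart, and members of multigene families such as the actins, myosin heavy chains and ribosomal proteins may share reads. Of 50559 mouse symbols shared with the GENCODE M21 annotation of mm10, 1387 (2.74%) have the same start and end there, so no mouse coordinates are given. Human coordinates are those of the deposited table, on GRCh38 per the labels, and mark the whole gene.

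Library totals ran from 32795699 to 43827517 counts in C2C12 and from 33030258 to 48546621 in LHCN-M2. Rows that shared a symbol with another row (959 in C2C12 and 1745 in LHCN-M2) held 0.154% and 0.0412% of the counts. The human table has 27 symbols in the form of dates; these genes were tested by their identifier and not matched between the lines. The libraries of a group were compared pair by pair with a chi-square over genes. The value per degree of freedom ran from 7.19 to 26.1 in C2C12 and from 6.52 to 171.2 in LHCN-M2, so no pair agreed within sampling noise, as copies of 1 library would. This does not show that the libraries come from separate cultures, and separate preparations of 1 culture may differ as much.

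Genes were tested within each line with edgeR 4.0.16 (R 4.3.3): filterByExpr left 17065 C2C12 and 18214 LHCN-M2 genes, holding over 99.9% of the counts, library sizes were scaled by TMM, and the quasi-likelihood test was fitted to all 12 libraries of a line with 1 coefficient per day. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. No replicate block was used, because the labels do not say that a replicate number marks a shared culture or day. Levels are CPM, computed here from the deposited counts with TMM-scaled library totals, as mean and SD over the 4 libraries of a group. Fold changes are on the log2 scale with their standard error (SE). Where a group held 0 counts, the fold is a lower bound against 3 counts over the group; where it held 1 to 3 counts, the ratio is given with its 95% counting interval. Such intervals and floors cover counting error only.

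The lines were compared on symbols that match when case is ignored and occur once in each table: 16602 symbols, of which 10953 were tested. Matching by symbol is not an orthology table. The difference between the fold changes of the lines was tested in 1 edgeR fit of all 24 libraries as an interaction, with normalization factors computed within each line. Day 6 of C2C12 and day 12 of LHCN-M2 are the last days of each line and are not the same time.

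The 30 gene lists (636 entries) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 180 tests within the lines, or over the tests between the lines. They cover myogenic regulators, sarcomere, excitation-contraction coupling, neuromuscular junction, dystrophin complex, muscle creatine and energy metabolism, glycolysis, oxidative phosphorylation, citric acid cycle, fatty acid oxidation, mitosis, DNA replication, cell cycle inhibitors, myogenesis inhibitors, cholesterol synthesis, unfolded protein response, interferon response, p53 targets, immediate early genes, lysosome and autophagy, heat shock, IGF and growth factors, muscle RNA splicing regulators and ribosomal proteins. Markers of other cell types were fibroblast and matrix, smooth muscle, adipocyte, bone and cartilage, neural, and immune and endothelial genes. All 636 entries were found in the human table and all but 2 in the mouse table. A member is "measured" if it passed the filter. Within the lines, medians of lists are also given with members at 0 counts set to their bound, where that moves them. Medians of the difference between the lines use fitted values for all members.

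The groups, tests, lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. Named genes were a panel of 15 muscle and cell cycle genes with 3 genes that bear on the origin of the lines (TERT, CDK4, CDKN2A); per comparison, the 5 genes with the largest rise and the 5 with the largest fall among genes past the threshold that reach a mean of 10 CPM in the higher group, show no overlap between the libraries of the groups and have a gene symbol rather than a clone or model name; and up to 3 members per list and direction under the same criteria. Between the lines, the 5 genes with the largest smaller rise in both, the 5 with the largest smaller fall, and the 5 at either end of the difference were taken. XIST and Y-linked genes were left out, and a few other genes that the rule names are not reported here.

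Alternatives were RLE and upper quartile scaling, no filter and a stricter filter (10 CPM in at least 4 libraries), DESeq2 1.42.0, limma-voom, a test against a 2-fold change, a replicate block, fits of the 8 libraries compared, leaving out each library in turn, and camera with an estimated correlation. Fits without both LHCN-M2 libraries that stand apart, with list tests adjusted over the 90 tests of that line, and a split of the day 1 libraries for transient genes were added after the data were seen. The number of calls was also counted over other splits of the libraries (35 per comparison, or 100 draws), and overlaps of calls that share libraries were set beside 20 simulations of unchanged groups. The tests were tested on simulated counts with 200 changed genes per comparison. In C2C12 day 6 vs day 0 (17065 genes), 88.6% of 4-fold and 69.2% of 2-fold changes were recovered and 9.94% of the calls were false, against a nominal 5%. In LHCN-M2 day 12 vs day 0 (18214 genes), 78.0% and 67.6% were recovered and 4.55% of the calls were false. In the interaction at the last day (10953 genes), 94.4% and 84.1% were recovered and 4.91% of the calls were false. The real comparisons within a line called 39.8% to 65.6% of the genes, far more than the 200 changed here. The simulated counts also held no library that stands apart, so these rates need not hold for the real comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.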

Results

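The data follow 2 established myoblast lines over differentiation. C2C12 is a mouse line and LHCN-M2 a human line immortalised with TERT and CDK4. The design compares each line with itself over time and the lines with each other. Polyadenylated RNA was counted per gene in 4 libraries per group: C2C12 at days 0, 1 and 6, and LHCN-M2 at days 0, 1 and 12. Library totals in C2C12 were 32795699 to 39597995 counts at day 0, 38243536 to 43827517 at day 1 and 34159505 to 42389647 at day 6. In LHCN-M2 they were 37460225 to 43446757 at day 0, 40403483 to 48546621 at day 1 and 33030258 to 44505597 at day 12. Values are means with SD over n = 4 libraries, and p-values are adjusted values of edgeR for genes and of camera for gene lists.

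The days of each line separated on the first components of log2 CPM, which held 57.8% and 16.4% of the variance in C2C12 and 56.1% and 18.3% in LHCN-M2. The third component of LHCN-M2 (5.87%) set replicate 2 of day 0 apart from its group, at -72.5 against 19.1 to 29.9 for the other day 0 libraries. On the same component, replicate 1 of day 12 lay at -22.3 against 4.41 to 9.27. TERT stood at 1161 ± 333.0 CPM in LHCN-M2 at day 0, and CDKN2A, a cell cycle inhibitor gene, at 323.2 ± 94.0 CPM. CDK4 stood at 94.3 ± 11.03 CPM in LHCN-M2 and at 318.9 ± 19.05 CPM in C2C12 at day 0. Tert stood at 0.801 ± 0.394 CPM in C2C12 at day 0. Reads of the lines were mapped to different genomes, so these CPM values do not measure differences in level between the lines. In C2C12, Cdkn2a had 0 counts at every day, which allows at most 0.0209 CPM at day 0.

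**Figure D1:**
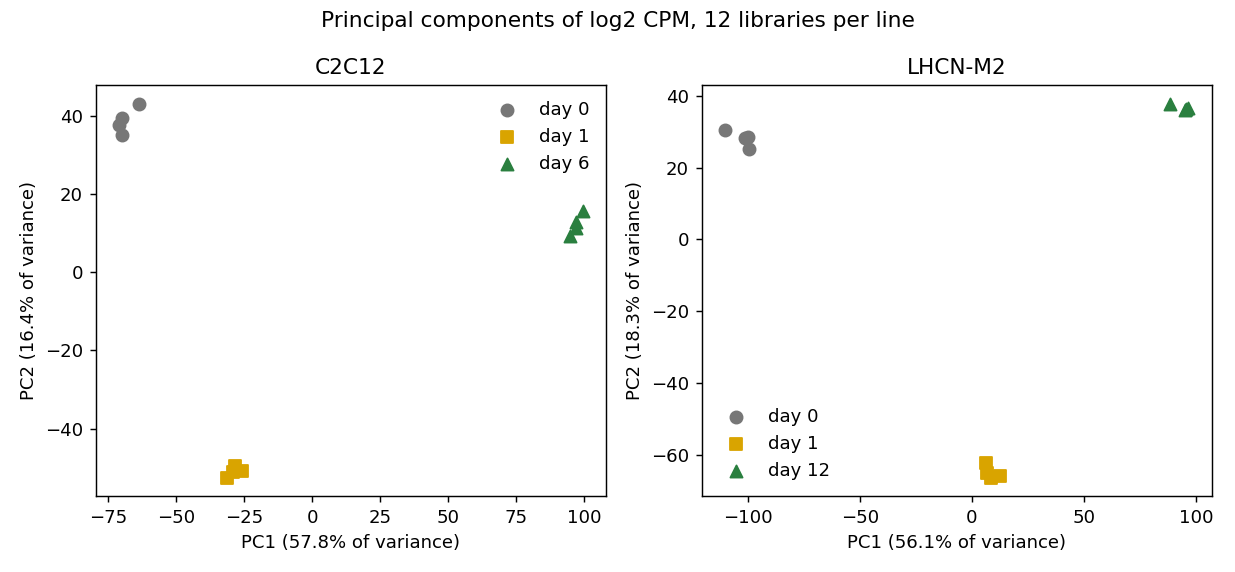
Principal components 1 and 2 of log2 CPM over the tested genes, C2C12 and LHCN-M2 apart, with 1 marker per library and its shape and colour by day. The 4 libraries of each day lie together and the days lie apart in both lines.

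After a day of differentiation, C2C12 showed higher levels of many muscle genes, but not of every muscle list, and slightly lower levels of mitosis genes. Embryonic myosin heavy chain, Myh3, rose from 0.541 ± 0.223 to 12.6 ± 2.199 CPM (log2 fold change 4.56, SE 0.18, adjusted p = 2.21e-14). Myogenin, Myog, a transcription factor of terminal differentiation, rose from 3.75 ± 0.281 to 13.7 ± 1.798 CPM (log2 fold change 1.87, SE 0.09, adjusted p = 1.09e-12). Asparagine synthetase, Asns, fell from 606 ± 22.2 to 45.9 ± 6.47 CPM (adjusted p = 2.38e-18). In all, 4421 of 17065 tested genes were higher at day 1 and 4161 lower, of which 838 and 964 changed at least 2-fold.

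Among genes that reached 10 CPM with no overlap between the libraries of the days, the largest rises were those of the matrix protein gene Cilp (log2 fold change 5.37), Myh3, the small proteoglycan decorin, Dcn (3.98), the chemerin receptor Cmklr1 (3.87) and Angptl4 (3.48), a secreted inhibitor of lipoprotein lipase. At the other end, the stress-response gene Trib3 fell by 5.17 on the log2 scale, the carbonic anhydrase gene Car6 by 5.16, Chac1, which degrades glutathione, by 4.52, the transcription factor Klf15 by 3.99 and Asns by 3.72. Among myogenic regulators, 13 of 16 measured genes rose and 1 fell (median log2 fold change 0.60, adjusted p = 0.000245). The members Myod1 and Mymk, the gene of the fusion protein myomaker, rose by 1.05 and 2.52 on the log2 scale. Of the sarcomere genes, 30 of 48 measured genes rose and 0 fell (median log2 fold change 1.53, or 1.22 with members at 0 counts set to their bound, adjusted p = 2.59e-07), among them cardiac alpha-actin, Actc1 (3.25), and skeletal alpha-actin, Acta1 (2.88). In the neuromuscular junction list 9 of 11 measured genes rose and 1 fell (median log2 fold change 0.76, adjusted p = 0.00391, and adjusted p = 0.0513 with an estimated correlation), with the acetylcholine receptor subunits Chrnb1 (1.59) and Chrna1 (1.51). Excitation-contraction coupling genes, which link the membrane to calcium release, had 12 of 18 members higher and 3 lower (median log2 fold change 0.71, adjusted p = 0.0253, and adjusted p = 0.0912 with an estimated correlation). The dystrophin complex and muscle creatine and energy metabolism had median log2 fold changes of 0.14 and -0.12 over the 14 genes of each matched between the lines.

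Mitosis genes moved together by a small amount: 29 of 30 fell and 0 rose (median log2 fold change -0.57, adjusted p = 5.02e-14). The kinetochore gene Ndc80 fell by 1.09, the centromeric histone Cenpa by 0.93 and cyclin B1, Ccnb1, by 0.62 on the log2 scale. The DNA replication genes split, with 13 of 31 higher and 7 lower (adjusted p = 0.104); Cdc6, which loads the replicative helicase, rose by 1.27. Cell cycle inhibitors had 7 of 11 lower and 1 higher (median log2 fold change -0.35, adjusted p = 0.00768, and adjusted p = 0.0967 with an estimated correlation), the member that rose being Cdkn1a, p21 (0.38). Of 22 cholesterol synthesis genes, 18 rose and 1 fell (median log2 fold change 0.44, adjusted p = 2.24e-07), among them Hsd17b7 (1.72). Heat shock genes had 11 of 18 higher (median log2 fold change 0.53, adjusted p = 0.0189, and adjusted p = 0.339 with an estimated correlation), and Hspa1b, an inducible HSP70 gene, rose by 2.60. Unfolded protein response genes had 11 of 22 lower and 5 higher (median log2 fold change -0.20, adjusted p = 0.002203, and adjusted p = 0.185 with an estimated correlation).

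The lists of oxidative phosphorylation, citric acid cycle, fatty acid oxidation and ribosomal proteins fell by small amounts. Oxidative phosphorylation had 36 of 47 genes lower (median log2 fold change -0.27, adjusted p = 1.07e-06, and adjusted p = 0.372 with an estimated correlation), and the citric acid cycle 12 of 16 (median log2 fold change -0.21, adjusted p = 0.0001297, and adjusted p = 0.179 with an estimated correlation). Fatty acid oxidation had 9 of 15 lower (median log2 fold change -0.25, adjusted p = 0.0113, and adjusted p = 0.272 with an estimated correlation), including the acyl-CoA dehydrogenase gene Acadm, which fell by 1.18. Ribosomal protein genes had 33 of 41 lower (median log2 fold change -0.25, adjusted p = 7.07e-06, and adjusted p = 0.446 with an estimated correlation). Neural genes had 4 of 6 higher (median log2 fold change 1.10, adjusted p = 0.00723, and adjusted p = 0.0667 with an estimated correlation), among them the tubulin Tubb3 (2.46) and the neurofilament Nefm (2.26). Across genes, the fold changes of this comparison had a Spearman rho of 0.177 with gene length, and genes are not independent replicates. Adjusted over the list alone, 38 oxidative phosphorylation, 13 citric acid cycle, 10 fatty acid oxidation, 8 cell cycle inhibitor, 2 cholesterol synthesis and 2 neuromuscular junction genes were lower, and 14 DNA replication genes were higher.

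By day 6, C2C12 expressed the contractile apparatus at high level, and its mitosis and DNA replication genes were not lower as groups. Myh3 reached 413 ± 32.6 CPM from 0.541 ± 0.223 (log2 fold change 9.60, SE 0.16, adjusted p = 1.06e-20) and Acta1 883 ± 50.5 CPM from 2.799 ± 0.513 (8.30, SE 0.18). Myog reached 143 ± 3.99 CPM (log2 fold change 5.25, SE 0.09, adjusted p = 2.09e-20) and Mymk 89.2 ± 7.03 CPM (7.03, SE 0.20). The proliferation marker Mki67 stood at 404 ± 52.8 CPM against 369.6 ± 32.1 at day 0 (adjusted p = 0.162), and without replicate 2 of day 6 its adjusted p was 0.00611. Of 17065 tested genes, 5650 were higher and 5540 lower, of which 1678 and 2311 changed at least 2-fold.

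The adult fast myosin gene Myh4 went from 0 counts to 152 ± 11.02 CPM, at least 7321-fold higher. Csrp3, a muscle LIM protein, was at least 791-fold higher, Tceal7 at least 739-fold and the myosin Myh2 at least 711-fold. The complement gene C3 fell by 9.87 on the log2 scale, the protease inhibitor Serpina3g by 7.42, and Cd74, the invariant chain, by 6.49. Of the sarcomere genes, 45 of 48 measured genes rose and 0 fell (median log2 fold change 6.62, or 6.55 with members at 0 counts set to their bound, adjusted p = 7.71e-20). Excitation-contraction coupling had 15 of 18 genes higher (median log2 fold change 3.87, adjusted p = 1.56e-06), including the calcium-binding proteins Casq2 (8.07) and Hrc (7.79). In the neuromuscular junction list, 10 of 11 measured genes rose and 1 fell (median log2 fold change 3.27, adjusted p = 0.000245), with the fetal acetylcholine receptor subunit Chrng at 6.37. Among myogenic regulators, 10 of 16 measured genes rose and 0 fell (median log2 fold change 0.86, adjusted p = 0.000245), including Mef2c (4.49) and Myod1 (2.75). The dystrophin complex had 8 of 15 genes higher and 3 lower (median log2 fold change 0.43, adjusted p = 0.0241, and adjusted p = 0.325 with an estimated correlation), including caveolin 3, Cav3 (8.62). Muscle creatine and energy metabolism had 9 of 16 genes higher (adjusted p = 0.0588), among them Ckm, muscle creatine kinase (6.35), and myoglobin, Mb (7.70).

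DNA replication genes were higher as a group: 25 of 31 rose and 4 fell (median log2 fold change 0.62, adjusted p = 1.96e-06, and adjusted p = 0.131 with an estimated correlation). Cdc6 rose by 1.99, cyclin E2, Ccne2, by 1.97 and the ribonucleotide reductase subunit Rrm2 by 1.96 on the log2 scale, while the polymerase subunit Pold1 fell by 0.71. Mitosis genes had 17 of 30 higher and 3 lower (median log2 fold change 0.19, adjusted p = 0.0234, and adjusted p = 0.357 with an estimated correlation). The inhibitor gene Cdkn1a rose to 309 ± 11.7 CPM from 113 ± 7.24. Glycolysis had 14 of 17 genes higher (median log2 fold change 0.49, adjusted p = 0.000497, and adjusted p = 0.137 with an estimated correlation), with Ldha, the muscle form of lactate dehydrogenase, at 1.26, while Ldhb fell by 2.83. Oxidative phosphorylation had 26 of 47 higher and 4 lower (median log2 fold change 0.22, adjusted p = 0.0152, and adjusted p = 0.686 with an estimated correlation). Heat shock genes had 13 of 18 higher (median log2 fold change 1.22, adjusted p = 3.33e-05, and adjusted p = 0.108 with an estimated correlation), among them Cryab (2.08). Cholesterol synthesis had 17 of 22 higher (median log2 fold change 0.56, adjusted p = 0.000325, and adjusted p = 0.133 with an estimated correlation), and immediate early genes 15 of 20 (median log2 fold change 0.74, adjusted p = 0.00341, and adjusted p = 0.145 with an estimated correlation).

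Markers of other cell types moved as well. Fibroblast and matrix genes had 19 of 25 lower and 4 higher (median log2 fold change -0.90, adjusted p = 0.0002702, and adjusted p = 0.307 with an estimated correlation): the collagen Col1a2 fell by 2.42, while Dcn rose by 4.86. Smooth muscle genes had 8 of 9 lower (median log2 fold change -2.18, adjusted p = 0.00341, and adjusted p = 0.114 with an estimated correlation), with leiomodin 1, Lmod1, falling by 3.98 and calponin, Cnn1, by 3.30. Adipocyte genes had 5 of 6 lower (median log2 fold change -1.11, adjusted p = 0.0234, and adjusted p = 0.102 with an estimated correlation), including lipoprotein lipase, Lpl, which fell by 1.58. Neural genes had 4 of 6 higher (median log2 fold change 2.89, adjusted p = 0.00948, and adjusted p = 0.07103 with an estimated correlation). The imprinted RNA H19 rose by 4.20 in the IGF and growth factor list, where 10 of 21 measured genes rose and 10 fell (adjusted p = 0.673). Ribosomal protein genes had 30 of 41 lower (median log2 fold change -0.37, adjusted p = 3.46e-05, and adjusted p = 0.483 with an estimated correlation), and fold changes had a Spearman rho of -0.154 with gene length.

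Among the lists not called by the test, 7 of 16 citric acid cycle genes rose and 5 fell (adjusted p = 0.819). Bone and cartilage had 2 of 5 higher and 1 lower (0.673), immune and endothelial 0 and 1 of 4 (0.795), interferon response 10 and 4 of 22 (0.142), and p53 targets 9 and 6 of 18 (0.673). Lysosome and autophagy had 11 higher and 7 lower of 25 (0.349), muscle RNA splicing regulators 10 and 3 of 14 (0.0588), and cell cycle inhibitors 6 and 3 of 11 (0.161). Signs differed for fatty acid oxidation (median -0.30, mean 0.25, test downward, adjusted p = 0.306), myogenesis inhibitors (median 0.01, mean 0.21, test downward, 0.872) and the unfolded protein response (median 0.14, mean -0.29, test upward, 0.7299). With the stricter filter on low counts, the fold changes of the genes it kept moved by a median of -0.11 on the log2 scale, so smaller list medians are to be read relative to that shift. Adjusted over the list alone, 27 oxidative phosphorylation, 26 DNA replication and 8 cell cycle inhibitor genes were higher and 31 ribosomal protein genes lower.

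Between day 1 and day 6 of C2C12, contractile genes rose further and cell cycle genes moved upward. Acta1 rose by 5.43 on the log2 scale, Myh3 by 5.03 and Myog by 3.38, the last at adjusted p = 2.55e-18. Ccnb1 rose from 109 ± 4.74 to 217 ± 5.84 CPM (log2 fold change 1.00, adjusted p = 1.75e-12). Of 17065 tested genes, 5592 were higher and 4888 lower (1261 and 1850 at least 2-fold).

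Myh4 rose from 2 to 23243 counts, a ratio of 12879 with a counting interval of 3565 to 106350. Abra was at least 757-fold higher and the fatty acid transporter Cd36 at least 669-fold. C3 fell by 10.86, the matrix metalloprotease Mmp9 by 8.13 and the acute-phase gene Saa3 by 6.44 on the log2 scale. Sarcomere genes had 44 of 48 higher (median log2 fold change 5.03, adjusted p = 3.28e-18), excitation-contraction coupling 14 of 18 (median log2 fold change 3.27, adjusted p = 4.5e-05) and the neuromuscular junction 9 of 11 (median log2 fold change 2.19, adjusted p = 0.000957). Of the mitosis genes, 29 of 30 measured genes rose and 1 fell (median log2 fold change 0.83, adjusted p = 1.3e-11), with anillin, Anln, at 1.35. DNA replication had 25 of 31 higher (median log2 fold change 0.59, adjusted p = 1.86e-06, and adjusted p = 0.131 with an estimated correlation), oxidative phosphorylation 44 of 47 (median log2 fold change 0.50, adjusted p = 6.75e-08, and adjusted p = 0.341 with an estimated correlation) and glycolysis 15 of 17 (median log2 fold change 0.87, adjusted p = 6.06e-05, and adjusted p = 0.0991 with an estimated correlation). The unfolded protein response had 18 of 22 higher (median log2 fold change 0.52, adjusted p = 2.85e-05, and adjusted p = 0.0866 with an estimated correlation), where Atf3 and Trib3 rose by 1.97 and 1.87. Smooth muscle genes had 8 of 9 lower (median log2 fold change -2.47, adjusted p = 0.000361, and adjusted p = 0.0688 with an estimated correlation) and fibroblast and matrix genes 20 of 25 (median log2 fold change -0.46, adjusted p = 8.74e-05, and adjusted p = 0.272 with an estimated correlation). The fold changes had a Spearman rho of -0.288 with gene length. Lists also called upward with the preset correlation only were myogenic regulators (9 of 16 genes higher, adjusted p = 0.0424, and adjusted p = 0.209 with an estimated correlation), dystrophin complex (11 of 15, 0.0159 and 0.303), muscle energy metabolism (11 of 16, 0.00807 and 0.108), citric acid cycle (11 of 16, 0.00966 and 0.341), cell cycle inhibitors (8 of 11, 0.00356 and 0.0761), neural (4 of 6, 0.0159 and 0.0866) and heat shock (14 of 18, 0.00308 and 0.239). Adjusted over the list alone, 45 sarcomere, 15 excitation-contraction coupling, 26 DNA replication and 19 unfolded protein response genes were higher.

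**Figure D2:**
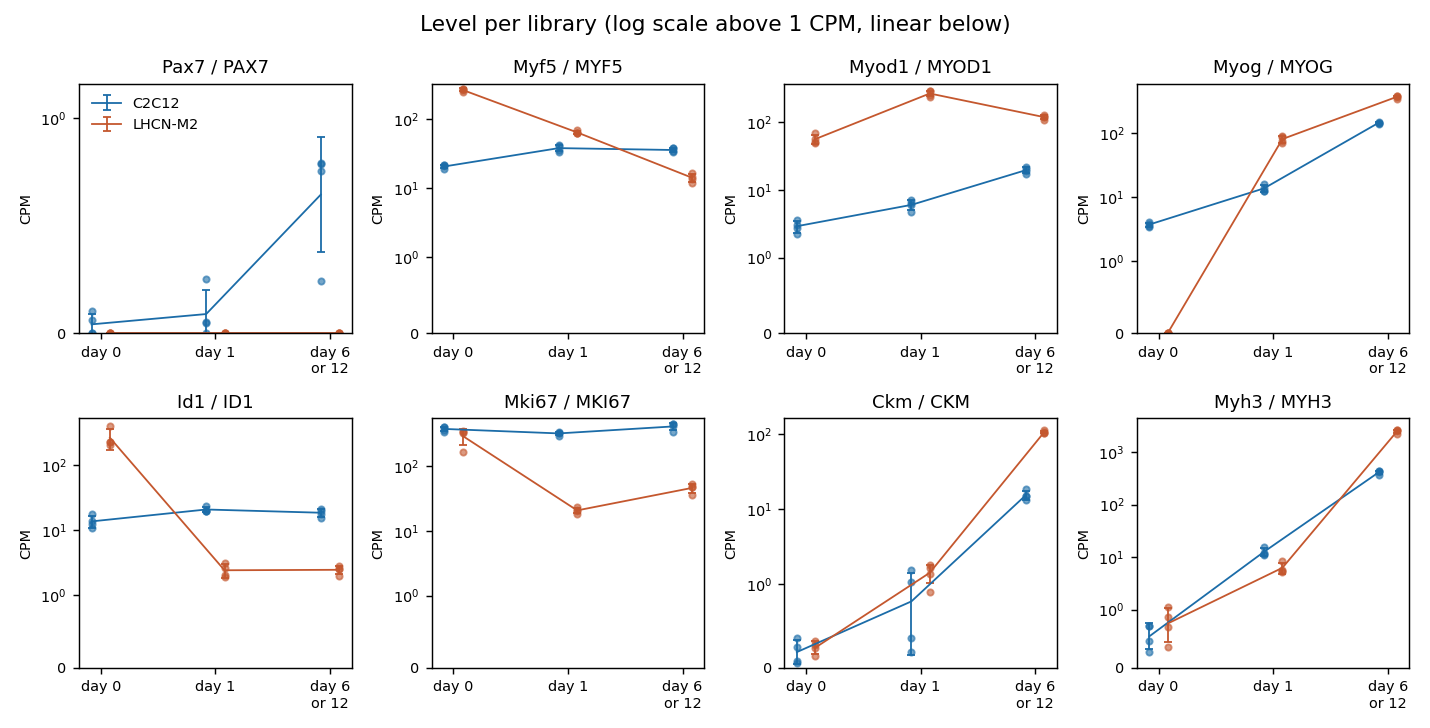
Levels of 8 genes in CPM by day (log scale above 1 CPM, linear below), C2C12 in blue and LHCN-M2 in orange, with 1 point per library, lines through the means and bars of 1 SD, n = 4. Myog and Myh3 rise in both lines, while ID1 goes from 265.4 to 2.44 CPM by day 1 in LHCN-M2 and Id1 from 13.8 to 20.96 CPM in C2C12.

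After a day of differentiation in LHCN-M2, most muscle regulators rose and cell division genes fell. MYOG (ENSG00000122180, chromosome 1, 203083132 to 203086036) went from 0 counts to 79.8 ± 9.78 CPM, at least 4152-fold higher. MKI67 fell from 289 ± 84.1 to 20.5 ± 2.03 CPM (by 3.82 on the log2 scale, SE 0.21, adjusted p = 8.66e-10). ID1 (ENSG00000125968, chromosome 20, 31605283 to 31606515), an inhibitor of myogenic transcription factors, fell from 265 ± 91.9 to 2.44 ± 0.5701 CPM (by 6.77, SE 0.25, adjusted p = 1.41e-11). Of 18214 tested genes, 4262 were higher and 4279 lower (1961 and 1326 at least 2-fold).

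The ryanodine receptor RYR1, the calcium release channel of muscle, rose by 10.29 on the log2 scale to 108 ± 17.6 CPM. The fast myosin light chain MYLPF rose by 9.94, CHRNG by 9.14 and the neuregulin receptor ERBB3 by 8.51. ANGPTL4 fell by 6.51, the hyaluronan synthase HAS1 by 5.20 and the kinetochore genes NUF2 and SPC25 had log2 fold changes of -4.69 and -4.50. Among myogenic regulators, 14 of 17 measured genes rose and 3 fell (median log2 fold change 0.95, adjusted p = 4.71e-05): MYOD1 rose by 2.23 and MYMX, the fusion peptide myomixer, by 5.08, while MYF5 fell by 2.06 to 64.6 ± 3.19 CPM. Of the sarcomere genes, 34 of 47 measured genes rose and 2 fell (median log2 fold change 3.08, or 3.03 with members at 0 counts set to their bound, adjusted p = 6.53e-13), including TNNI1, slow troponin I (7.26), and ACTA1 (5.40). Excitation-contraction coupling had 13 of 20 genes higher and 0 lower (median log2 fold change 1.53, adjusted p = 4.68e-07), the neuromuscular junction 11 of 12 higher (median log2 fold change 0.99, adjusted p = 4.71e-05) and the dystrophin complex 11 of 14 (median log2 fold change 1.35, adjusted p = 3.95e-06). Muscle creatine and energy metabolism had 10 of 15 higher (median log2 fold change 2.07, adjusted p = 9.46e-05), with the fatty acid binding protein FABP3 at 4.83.

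All 30 measured mitosis genes fell (median log2 fold change -3.45, adjusted p = 1.08e-24), among them CENPA, by 4.34 on the log2 scale, and CDC20, an activator of the anaphase-promoting complex, by 4.17. All 31 DNA replication genes fell (median log2 fold change -2.36, adjusted p = 1.52e-22), among them RRM2, by 3.97, and MCM10, by 3.92. The cell cycle inhibitor CDKN1C, p57, rose by 7.04 and GADD45G by 8.09; in their list 6 of 13 rose and 5 fell, with median -0.20, mean 0.93 and an upward test (adjusted p = 0.677). Cholesterol synthesis had 21 of 22 genes higher and 0 lower (median log2 fold change 1.65, adjusted p = 5.42e-15), including HMGCS1 (3.17). Glycolysis had 14 of 17 lower (median log2 fold change -0.99, adjusted p = 3.7e-08, and adjusted p = 0.0863 with an estimated correlation), with LDHA falling by 2.25. Interferon response had 13 of 21 higher (median log2 fold change 1.25, adjusted p = 0.00308, and adjusted p = 0.6002 with an estimated correlation), and lysosome and autophagy 17 of 25 (median log2 fold change 0.52, adjusted p = 0.001596, and adjusted p = 0.352 with an estimated correlation). Citric acid cycle genes had 9 of 16 lower (median log2 fold change -0.33, adjusted p = 0.00504, and adjusted p = 0.159 with an estimated correlation).

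Oxidative phosphorylation and ribosomal proteins crossed the threshold of the list test without both libraries that stood apart. Oxidative phosphorylation had 21 of 47 genes lower (median log2 fold change -0.29, adjusted p = 0.00587, and adjusted p = 0.718 with an estimated correlation); without replicate 2 of day 0 and replicate 1 of day 12 it had 9 higher and 20 lower (median -0.09, adjusted p = 0.129). Ribosomal proteins had 1 higher and 1 lower of 41 (median -0.06, adjusted p = 0.925), and without both libraries 35 higher and 0 lower (median 0.20, adjusted p = 0.000172, and adjusted p = 0.507 with an estimated correlation). Replicate 2 of day 0 held 164.0 CPM of MKI67 against 321.6 to 343.0 in the others, and 402.5 CPM of ID1 against 206.4 to 227.1. The fold changes had a Spearman rho of 0.223 with gene length. Without both libraries, a fit chosen after the data were seen, 5258 genes were higher and 4598 lower. Adjusted over the list alone, 15 glycolysis genes and 1 cholesterol synthesis gene were lower, 18 lysosome and autophagy genes were higher, and 0 ribosomal protein genes were called.

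At day 12, LHCN-M2 expressed contractile genes strongly, with cell division genes below their day 0 level. MYH3 (ENSG00000109063, chromosome 17, 10628526 to 10657309) reached 2496 ± 204 CPM from 0.7599 ± 0.3195 (log2 fold change 11.67, SE 0.26, adjusted p = 4.6e-14). MYOG reached 362 ± 16.4 CPM, at least 18896-fold higher, and MYMK 219 ± 10.53 CPM, at least 11399.6-fold. MYF5 (ENSG00000111049, chromosome 12, 80716912 to 80719673) fell by 4.24 on the log2 scale to 14.2 ± 2.09 CPM (SE 0.11, adjusted p = 1.25e-13), and MKI67 by 2.67 to 45.5 ± 7.03 CPM. Of 18214 tested genes, 4935 were higher and 5006 lower (2638 and 1779 at least 2-fold).

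Calsequestrin 2, CASQ2, which binds calcium in the sarcoplasmic reticulum, rose from 2 to 61245 counts, a ratio of 29986 with a counting interval of 8301 to 247607. The myosin chaperone UNC45B was at least 10633-fold higher, the calcium channel subunit CACNA1S at least 5891-fold and the sodium channel SCN4A at least 2615-fold. ID1 fell by 6.74 on the log2 scale, the sulfotransferase CHST1 by 7.69, NPTX2 by 5.79, the VEGF receptor KDR by 5.17 and the chromatin protein HMGA2 by 4.85. Of the sarcomere genes, 44 of 47 measured genes rose and 1 fell (median log2 fold change 8.23, or 7.86 with members at 0 counts set to their bound, adjusted p = 2.81e-26). Excitation-contraction coupling had 18 of 20 higher (median log2 fold change 7.89, or 6.55 with members at 0 counts set to their bound, adjusted p = 1.78e-13). Neuromuscular junction genes had 11 of 12 higher (median log2 fold change 1.40, adjusted p = 1.1e-05), with CHRNG at 11.33. Dystrophin complex genes had 11 of 14 higher (median log2 fold change 1.88, adjusted p = 3.42e-05, and adjusted p = 0.0503 with an estimated correlation), including DMD itself (3.61). Energy metabolism of muscle had 14 of 15 higher (median log2 fold change 3.65, adjusted p = 2.29e-08), with CKM at 8.81 and the muscle enolase ENO3 at 3.65. Among myogenic regulators, 13 of 17 measured genes rose and 3 fell (median log2 fold change 1.07, adjusted p = 0.000392, and adjusted p = 0.0685 with an estimated correlation).

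Glycolysis had 16 of 17 genes lower (median log2 fold change -1.43, adjusted p = 3.07e-09, and adjusted p = 0.0685 with an estimated correlation), among them LDHA, which fell by 2.12 on the log2 scale. All 31 DNA replication genes were lower (median log2 fold change -2.30, adjusted p = 8.7e-18), and 29 of 30 mitosis genes (median log2 fold change -2.49, adjusted p = 4.43e-17, and adjusted p = 0.0608 with an estimated correlation), including the kinase AURKB, which fell by 3.56. CDKN1A rose to 2254 ± 75.4 CPM from 893 ± 79.5, and CDKN1C by 8.41 on the log2 scale. Cholesterol synthesis had 16 of 22 higher (median log2 fold change 0.49, adjusted p = 2.08e-05). Matrix genes had 17 of 26 higher and 6 lower (median log2 fold change 0.64, adjusted p = 0.00283, and adjusted p = 0.1102 with an estimated correlation), with the proteoglycan lumican, LUM, at 4.97. In the IGF and growth factor list 14 of 22 measured genes rose and 5 fell (median log2 fold change 0.94, adjusted p = 0.0248, and adjusted p = 0.0866 with an estimated correlation), with IGFBP5, an IGF binding protein, at 8.91. Ribosomal proteins had all 41 genes lower (median log2 fold change -0.63, adjusted p = 3.74e-06, and adjusted p = 0.562 with an estimated correlation), with a Spearman rho of 0.222 between fold changes and gene length. The splicing regulator RBFOX1 rose by 5.79 and PTBP1, a repressor of muscle exons, fell by 1.27, in a list where 7 of 15 measured genes rose and 5 fell (adjusted p = 0.619).

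Lists not called were oxidative phosphorylation (adjusted p = 0.202), citric acid cycle (0.467), fatty acid oxidation (0.187), smooth muscle (0.142), adipocyte (0.516), immune and endothelial (0.355), unfolded protein response (0.3099), p53 targets (0.472), immediate early (0.867) and cell cycle inhibitors (0.364). Lysosome and autophagy had an adjusted p of 0.142, and 0.0495 without both libraries that stood apart, or 0.452 there with an estimated correlation. Signs differed for myogenesis inhibitors (median 0.35, mean -0.27, adjusted p = 0.694), bone and cartilage (-0.98 and 1.07, 0.509), neural (0.06 and 0.67, 0.965) and heat shock (-0.26 and 0.25, 0.758), all with a downward test. Interferon response had a median of -0.06 and a mean of -0.05 with an upward test (0.772). Without both libraries, 5468 genes were higher and 5100 lower. Adjusted over the list alone, 45 sarcomere, 19 excitation-contraction coupling, 15 muscle energy and 8 splicing regulator genes were higher, and 10 oxidative phosphorylation, 7 matrix and 6 splicing regulator genes lower.

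**Figure D3:**
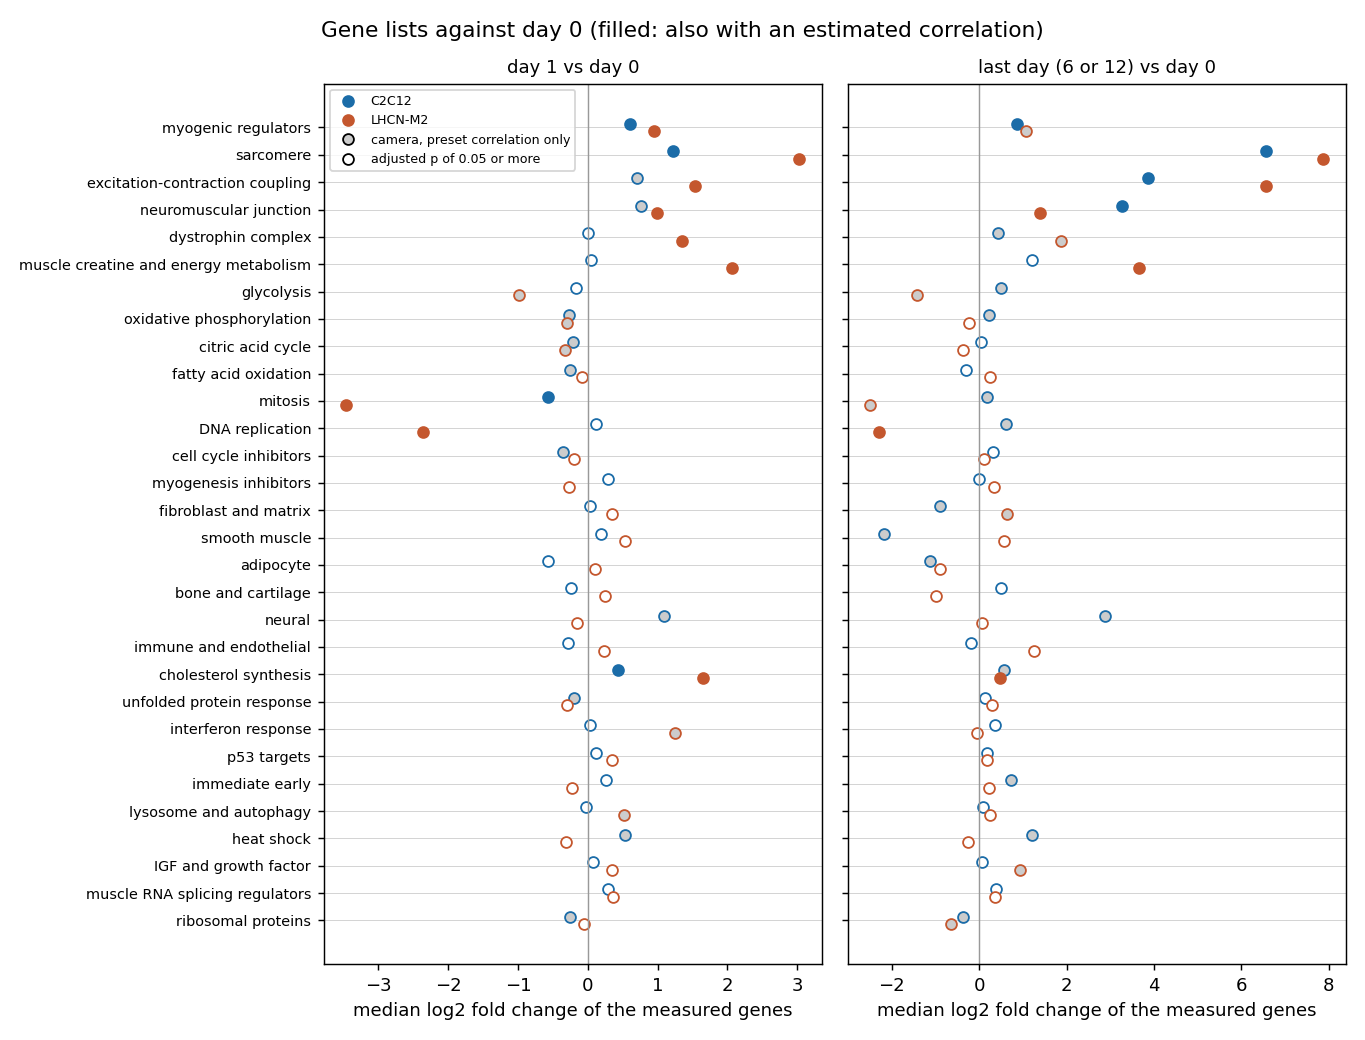
Median log2 fold change of the members of 30 gene lists against day 0, at day 1 on the left and at the last day on the right, with members at 0 counts set to their bound. Filled markers are lists called also with an estimated correlation, grey markers those called with the preset correlation only and open markers those not called; sarcomere lies farthest to the right at the last day in both lines.

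From day 1 to day 12 of LHCN-M2, contractile genes rose while cholesterol synthesis genes fell back. MYH3 rose by 8.65 on the log2 scale (SE 0.23, adjusted p = 1.32e-12), CKM by 6.24 and MYOG by 2.18. MYOD1 fell by 1.16 and MYF5 by 2.19. ID1 stayed at 2.48 ± 0.377 CPM against 2.44 ± 0.5701 (adjusted p = 0.9499). Of 18214 tested genes, 3814 were higher and 3433 lower (1508 and 898 at least 2-fold), and without both libraries that stood apart 4679 and 4399.

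MYBPC1, slow myosin-binding protein C, was at least 912-fold higher, CAPN6 at least 746-fold and triadin, TRDN, at least 666-fold. The actin nucleator LMOD2 rose from 2 to 6253 counts, a ratio of 3467 with a counting interval of 959 to 28636. Heme oxygenase, HMOX1, fell by 3.71 on the log2 scale from 401 ± 21.2 to 30.7 ± 2.17 CPM, NPTX2 by 2.84 and the prostaglandin receptor PTGER2 by 2.66. Sarcomere genes had 45 of 47 higher (median log2 fold change 4.53, adjusted p = 1.89e-27), excitation-contraction coupling 17 of 20 (median log2 fold change 2.87, adjusted p = 3.97e-12) and muscle energy metabolism 12 of 15 (median log2 fold change 1.63, adjusted p = 6.55e-06). Cholesterol synthesis had 20 of 22 lower (median log2 fold change -1.08, adjusted p = 2.56e-13), with lanosterol synthase, LSS, falling by 2.01. Interferon response had 16 of 21 lower (median log2 fold change -1.21, adjusted p = 0.00198, and adjusted p = 0.592 with an estimated correlation). Unfolded protein response genes had 13 of 22 higher (median log2 fold change 0.34, adjusted p = 0.00162), with CHAC1 at 3.95 and TRIB3 at 3.61. Mitosis genes had 26 of 30 higher (median log2 fold change 0.95, adjusted p = 6.08e-10, and adjusted p = 0.133 with an estimated correlation), and MKI67 rose by 1.15. Ribosomal proteins had 36 of 41 lower (median log2 fold change -0.61, adjusted p = 9.42e-09, and adjusted p = 0.4597 with an estimated correlation). Neuromuscular junction genes had 7 of 12 higher (median log2 fold change 0.56, adjusted p = 0.007404, and adjusted p = 0.131 with an estimated correlation). Fibroblast and matrix genes had 13 of 26 higher and 6 lower (median log2 fold change 0.26, adjusted p = 0.03496, and adjusted p = 0.245 with an estimated correlation), and smooth muscle genes 5 of 8 higher and 1 lower (median log2 fold change 0.94, adjusted p = 0.0430, and adjusted p = 0.131 with an estimated correlation). Fold changes had a Spearman rho of 0.0288 with gene length. Fatty acid oxidation had 6 of 15 higher (median log2 fold change 0.31, adjusted p = 0.0299, and adjusted p = 0.352 with an estimated correlation), and an adjusted p of 0.05905 without both libraries. Glycolysis (8 of 17 lower, adjusted p = 0.0588) and p53 targets (8 of 19 lower, adjusted p = 0.126) had adjusted p of 0.0205 and 0.0495 without both libraries, and of 0.377 and 0.312 there with an estimated correlation. Adjusted over the list alone, 21 cholesterol synthesis, 37 ribosomal protein, 9 glycolysis and 7 matrix genes were lower.

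Of the 180 list tests, 87 passed with the preset correlation and 32 with an estimated one. With the estimated correlation, sarcomere was called in all 6 comparisons. Excitation-contraction coupling was called in each but day 1 vs day 0 of C2C12. Mitosis was called in C2C12 for day 1 vs day 0 and day 6 vs day 1, and in LHCN-M2 for day 1 vs day 0. Cholesterol synthesis was called in C2C12 for day 1 vs day 0 and in each LHCN-M2 comparison. The other lists called with it are those given above without a second adjusted p. Without both LHCN-M2 libraries that stood apart, 7 of the 20 LHCN-M2 calls with the estimated correlation were kept, and all 20 lists kept their direction. For the lost calls, the median log2 fold change without both libraries is given against that with all libraries. Kept were sarcomere in each comparison, excitation-contraction coupling for day 12 vs day 0 and day 12 vs day 1, muscle energy metabolism for day 12 vs day 0 and cholesterol synthesis for day 1 vs day 0. Lost at day 1 vs day 0 were myogenic regulators (adjusted p = 0.133, median 0.98 against 0.95), excitation-contraction coupling (0.05905, median 1.63 against 1.53), neuromuscular junction (0.0917, median 0.98 against 0.99), dystrophin complex (0.0993, median 1.35 against 1.35), muscle energy metabolism (0.05905, median 2.15 against 2.07), mitosis (0.05905, median -3.49 against -3.45) and DNA replication (0.05905, median -2.29 against -2.36). Lost at day 12 vs day 0 were neuromuscular junction (0.0724, median 1.43 against 1.40), DNA replication (0.0724, median -2.26 against -2.30) and cholesterol synthesis (0.0993, median 0.54 against 0.49), and at day 12 vs day 1 muscle energy metabolism (0.0569, median 1.65 against 1.63), cholesterol synthesis (0.0568, median -1.07 against -1.08) and the unfolded protein response (0.0724, median 0.39 against 0.34).

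The comparison between the lines asks whether mouse and human myoblasts change alike. At day 1, sarcomere, excitation-contraction coupling and muscle energy genes changed more upward in LHCN-M2 and mitosis genes fell further there. These are differences of fold changes, not of levels, and a low day 0 level allows a larger fold change. ACTA1 went from 0.106 to 4.45 CPM in LHCN-M2 and from 2.80 to 20.5 CPM in C2C12, with a difference of 2.52. MYOG went from 0 counts to 79.8 CPM in LHCN-M2 and from 3.75 to 13.7 CPM in C2C12. ID1 had a log2 fold change of 0.61 in C2C12 and -6.77 in LHCN-M2, a difference of -7.37 (SE 0.28, adjusted p = 1.28e-16). MKI67 differed by -3.59 (SE 0.23, adjusted p = 1.49e-12), and MYF5 by -2.94 (SE 0.12). Of 10953 matched genes, 2849 changed more upward in LHCN-M2 and 3722 less.

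Among the named genes, ANGPTL4 had the largest negative difference, -9.99 (SE 0.33), and others were HAS1 (-5.80) and CDC6 (-4.49). RYR1 (9.21), GADD45G (8.44) and COL14A1 (8.38), a fibril-associated collagen, lay at the other end. MYH3 rose in both lines, by 4.56 in C2C12 and less, by 3.03, in LHCN-M2 (difference -1.54, SE 0.36, adjusted p = 0.000801). MYMX rose more in LHCN-M2 (difference 3.93). PTX3, a secreted pattern recognition protein, fell in both (-2.18 and -2.03), as did MTHFD2 of mitochondrial folate metabolism (-2.84 and -1.35). All 30 of 30 mitosis genes changed less upward in LHCN-M2 (median difference -2.79, adjusted p = 2.49e-18), as did 31 of 31 DNA replication genes (-2.62, adjusted p = 2.46e-18). Sarcomere (1.59, adjusted p = 0.000116), excitation-contraction coupling (1.82, adjusted p = 0.00332), muscle energy metabolism (1.17, adjusted p = 0.00571) and cholesterol synthesis (1.24, adjusted p = 1.43e-10) changed more upward in LHCN-M2, also with an estimated correlation. Myogenic regulators (0.66, adjusted p = 0.0268) and the dystrophin complex (1.35, adjusted p = 0.000162) did so with the preset correlation only. With an estimated correlation their adjusted p were 0.0913 and 0.0507. The neuromuscular junction list was not called (0.10, adjusted p = 0.245). At either day, the list tests between the lines were not repeated without both LHCN-M2 libraries that stand apart. Their medians use fitted values, also for members at 0 counts. Across genes, fold changes of the lines had a Pearson r of 0.132 and a Spearman rho of 0.0623. Of 3933 genes called in both lines, 52.1% had the same direction, with 972 higher in both where independent calls would give 908.6.

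At the last day, the lines shared the rise of the contractile genes and parted in glycolysis and DNA replication. Of 45 matched sarcomere genes, 40 were higher in both lines. Of 31 DNA replication genes, 25 were higher in C2C12 and lower in LHCN-M2 (median difference -3.08, adjusted p = 4.49e-15). Glycolysis had 11 of 15 genes higher in C2C12 and lower in LHCN-M2 (-2.15, adjusted p = 6.98e-06). Of 10953 matched genes, 3419 changed more upward in LHCN-M2 and 4376 less.

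HMGA2 rose by 2.14 in C2C12 and fell by 4.85 on the log2 scale in LHCN-M2 (difference -6.99, SE 0.13, adjusted p = 1.9e-22). ANGPTL4 (-8.50), ID1 (-7.18), CTHRC1 (-6.55) and MYF5 (-5.04) also changed less upward in LHCN-M2. CAPN6 was at least 658-fold higher at day 12 of LHCN-M2 and had a log2 fold change of -1.13 in C2C12, and WNT10A was at least 716-fold higher against -0.93. MYH3 (9.60 and 11.67) and the embryonic light chain MYL4 (8.73 and 11.11) rose in both, while ID3 (-2.54 and -3.92) and FBLN1 (-2.58 and -2.60) fell in both. The difference for MEF2C was -0.25 (adjusted p = 0.244) and for CDKN1A -0.11 (adjusted p = 0.253). Sarcomere (2.02, adjusted p = 0.00214), excitation-contraction coupling (4.42, adjusted p = 0.000705), muscle energy metabolism (1.87, adjusted p = 0.00135) and smooth muscle (2.45, adjusted p = 0.00721) changed more upward in LHCN-M2, also with an estimated correlation. Members at 0 counts entered these medians at fitted values and not at their bound, so the sizes are uncertain. Mitosis differed by -2.67 (adjusted p = 4.22e-13, and adjusted p = 0.0507 with an estimated correlation). Across genes, r was 0.292 and rho -0.0146, and for the changes from day 1 to the last day r was 0.339 and rho 0.247. Of 5330 genes called in both lines, 45.6% had the same direction, with 1221 higher in both where independent calls would give 1293.

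**Figure D4:**
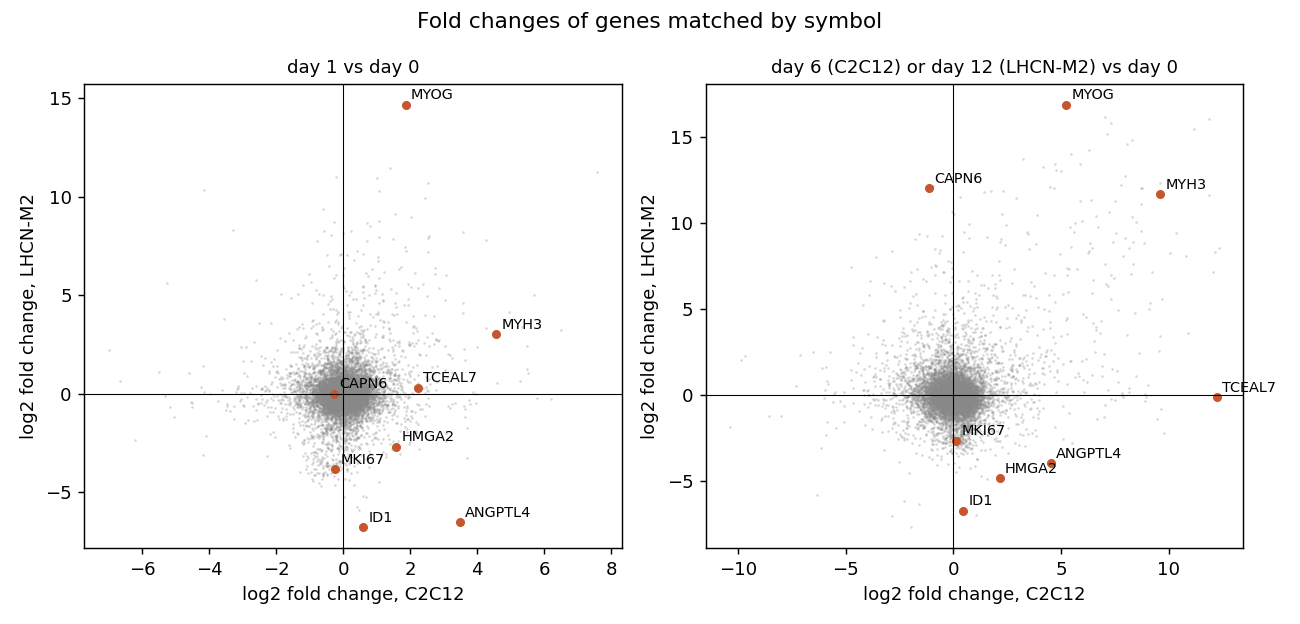
Log2 fold changes of 10953 matched genes in C2C12 (x axis) and LHCN-M2 (y axis), day 1 vs day 0 and last day vs day 0, with 1 point per gene and 8 genes named. Genes with 0 counts at a day are drawn at their fitted value; MYH3 lies high in both lines, and ID1 and ANGPTL4 lie low in LHCN-M2 only.

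Many genes called at day 1 were called in the same direction at the last day, and others in the opposite direction. Of 6639 C2C12 genes called at both days, 1497 had opposite directions, and of 6505 LHCN-M2 genes, 447. In C2C12, 2683 genes were higher and 2459 lower at both days, where independent calls would give 1464 and 1351. In LHCN-M2 the counts were 2923 and 3135 against 1155 and 1176. These comparisons share their day 0 libraries; with day 0 split between them, the counts were 1910 and 1987 in C2C12 (1129 and 1029 if independent) and 2302 and 2561 in LHCN-M2 (966.8 and 941.5). Simulations of unchanged groups, which hold no effects, gave 0 shared genes.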

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

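Among the tests of this part, those of library size for the DNA replication genes, of day 12 RNA in the day 0 library and of wrong symbol matches were chosen before their result was seen, and the other tests of explanations were chosen after. A library far from the others was looked for in 144 sets, each holding 1 measure in the 4 libraries of a group. The measures were library values, a principal component and the CPM of named genes. Of these sets, 16 had such a library. A rate of 1 in 20 would give 7.2, but this is no valid chance value. The measures are related, several of the 16 come from the same library, and sets without any counts could not pass.

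DNA replication genes of C2C12 were higher at day 6 than at day 0, with a median log2 fold change of 0.62, while those of LHCN-M2 fell. The choice of scaling was not the whole cause, since the lowest median over 3 scalings was 0.57. As the TMM factors of C2C12 ran only from 0.967 to 1.02, another choice could move the median little. Thinning all libraries to the smallest total gave 0.59. It lowers the counts of each library in proportion, so it could hardly change this median and cannot decide about library size. With an estimated correlation the adjusted p of the list was 0.131. The amount of RNA per cell and continued division of some cells stay open as untested, and either may contribute.

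Replicate 2 of LHCN-M2 day 0 lay apart from its group, with 491 of 9673 genes more than 1 log2 unit from the mean of the others. Its deviation had a Spearman rho of -0.588 with gene length, so a length-related bias in this library is a candidate explanation. The correlation with gene length was of like size in replicate 1 of C2C12 day 0 (-0.550), replicate 2 of C2C12 day 6 (-0.521) and replicate 1 of LHCN-M2 day 12 (-0.574), where 28, 9 and 14 genes deviated as much. How many genes a length-related bias accounts for was not tested. RNA of day 12 cells is excluded, since genes of day 12 stood at a median of 0.0294% of their day 12 level over 27 genes, and so is library size, since its total of 40.1 M counts lay inside the range of the group. No biological explanation was tested.

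Fold changes of the lines were weakly related at the last day, with r of 0.292 and rho of -0.0146 across genes. The strongest relation was that of the changes from day 1 to the last day, with r of 0.339 and rho of 0.247. The stricter filter left r at 0.316, so genes with low counts at every day were not the whole cause. That filter keeps genes that are low at some days and high at others, so it cannot decide about those. At day 1 it raised r from 0.132 to 0.202. Wrong symbol matches are excluded as the whole cause, since the day 0 levels of the same 10953 genes (log2 CPM) had an r of 0.668 between the lines. Lines that move at different speeds cannot be told apart from lines that differ: pairing day 6 vs day 0 of C2C12 with day 12 vs day 1 of LHCN-M2 raised r by 0.0340 and rho by 0.206, and the days sampled are too few to align. Species, line and medium stay open as untested.

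Libraries far from the others of their group were replicate 2 of LHCN-M2 day 0 in genes with a count (22122 against 22693 to 22809), TMM factor (0.941 against 0.984 to 0.993) and component 3 (-72.5 against 19.1 to 29.9). The same library stood apart in ID1 (402.5 CPM against 206.4 to 227.1), MKI67 (164.0 CPM against 321.6 to 343.0) and CDKN2A (462.8 CPM against 265.7 to 294.6). Replicate 1 of LHCN-M2 day 12 stood apart in component 3 (-22.3 against 4.41 to 9.27), MEF2C (300.1 CPM against 374.1 to 386.2) and TERT (534.7 CPM against 719.9 to 750.7). In LHCN-M2 day 1, replicate 2 had 69.3 CPM of MYF5 (62.6 to 63.7) and 508.8 CPM of TERT (532.9 to 535.5), and replicate 1 had 8.39 CPM of MYH3 (5.30 to 5.76). In C2C12, replicate 1 of day 1 stood apart in component 3 (6.16 against -1.38 to -0.427) and Id1 (23.8 CPM against 19.8 to 20.1), replicate 2 of day 0 in Myf5 (18.6 CPM against 20.97 to 21.4) and replicate 4 of day 6 in Pax7 (0.242 CPM against 0.752 to 0.791).

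The lines differed by the test of the difference itself in 2849 genes changed more upward and 3722 less in LHCN-M2 at day 1, and in 3419 and 4376 at the last day. Lists differed at day 1 by a median of 1.59 (sarcomere), 1.82 (excitation-contraction coupling), 1.17 (muscle energy metabolism), -2.79 (mitosis), -2.62 (DNA replication) and 1.24 (cholesterol synthesis). At the last day they differed by 2.02 (sarcomere), 4.42 (excitation-contraction coupling), 1.87 (muscle energy metabolism), -2.15 (glycolysis), -3.08 (DNA replication) and 2.45 (smooth muscle).

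Other splits of the libraries were counted for each number of genes. In each of the 6 comparisons within a line, fitted to the 8 libraries of its days, 1 of 35 splits, the real one, gave as many genes. This is the lowest share that 35 splits allow. The other splits mix the days in each group, which widens the spread within a group and leaves few genes to call. The counts show that the libraries group by day. They do not bear on whether the replicates are separate cultures, or on a batch shared by the libraries of a day. The real splits called 8508, 10857 and 10396 genes in C2C12 (day 1 vs day 0, day 6 vs day 0, day 6 vs day 1) and 7733, 8993 and 9022 in LHCN-M2 (day 1 vs day 0, day 12 vs day 0, day 12 vs day 1), and the highest other split called 1 gene in the C2C12 day 1 comparison and 0 in the others. For the differences between lines, 1 of 100 splits gave as many, with 6255 genes against 4196 at day 1 and 7487 against 4019 at the last day. These splits shuffled each line on its own, so a split may keep the days of 1 line apart. Which splits did so was not counted. For genes shared by the days and transient genes, 1 of 100 draws gave as many in each line, with 0 as the highest other value. In the comparisons within a line, splits that mixed the days called almost no genes. Draws that mix the days of a line would therefore give about 0 whether or not calls are shared or transient, and these values are no separate support. For gene lists, adjusted here over the 90 tests of each line, 1 of 100 draws gave as many in C2C12 (51 called, highest other 43), and 2 of 100 in LHCN-M2 (39 called, highest other 41). The other draws still called at least 8 lists in C2C12 and 9 in LHCN-M2. Lists thus pass with the preset correlation also in groups that mix the days, so the number of lists called says little by itself. Draws with an estimated correlation were not counted.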

How the results depend on the processing

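Fits without both LHCN-M2 libraries that stand apart and the split of the day 1 libraries for transient genes were chosen after the data were seen, and all other settings were planned. For counts and correlations, 415 of 473 alternative values were the same and 58 moved. For a count, the same means within 1.5 times the main count. For a correlation it means within 1 SD of its values with each library left out in turn. Leaving out each library in turn gave 288 of the 473 values, of which 13 moved, so most values that moved came from the other settings. Among named genes within a line, 17747 of 17877 alternative values kept their direction and side of the threshold, 118 lost the call, 12 gained it and 0 reversed; between the lines it was 2304 of 2342, with 32 weaker, 5 stronger and 1 reversed. The result that reversed was that of LMOD2 at the last day, which had 1 count at day 0 of LHCN-M2 and 6 in C2C12, so its fitted difference is no measure of size: leaving out each library in turn gave -0.56 (without C2C12 day 0 replicate 4) to 4.86. Ribosomal proteins at day 1 vs day 0 of LHCN-M2 reversed without both libraries apart (adjusted p = 0.000172, but 0.507 with an estimated correlation). The cause was not tested for any of these.

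Requiring also a 2-fold change left 838 genes higher and 964 lower for day 1 vs day 0 of C2C12, 1678 and 2311 for day 6 vs day 0, and 1261 and 1850 for day 6 vs day 1. In LHCN-M2 it left 1961 and 1326 for day 1 vs day 0, 2638 and 1779 for day 12 vs day 0, and 1508 and 898 for day 12 vs day 1. A test against a 2-fold change gave, in the same order, 267 and 307, 1090 and 1281, and 754 and 902 in C2C12, and 1001 and 747, 1749 and 1006, and 813 and 271 in LHCN-M2. Both thresholds call fewer genes by construction. The stricter filter, which tests fewer genes, left 3740 genes higher at day 6 vs day 0 of C2C12 and 3258 at day 12 vs day 0 of LHCN-M2. Genes shared by both days with a 2-fold change were 513 higher and 585 lower in C2C12, and 1354 and 926 in LHCN-M2. Differences between lines of at least 2-fold were 1311 more and 1331 less at day 1, and 1894 and 2023 at the last day. Without a fold requirement, transient genes were 1841 up then down and 1861 down then up in C2C12, and 1348 and 1275 in LHCN-M2. With the day 1 libraries split between the comparisons, which leaves fewer libraries in each, 108 genes of C2C12 fell and then rose. Of 87 list calls, 32 held with an estimated correlation; in LHCN-M2 it was 20 of 39, and 7 without both libraries apart.

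Across genes, r between the lines was 0.202 at day 1 and 0.316 at the last day with the stricter filter, and 0.126 at day 1 without both libraries apart. Leaving out each library in turn gave r of 0.118 to 0.139 at day 1 and 0.282 to 0.299 at the last day. With a replicate block, 4322 genes were higher and 4059 lower at day 1 vs day 0 of C2C12, and 4069 and 4033 in LHCN-M2. Libraries of the same number had residual correlations of -0.0527 to 0.0386 in C2C12 and -0.100 to 0.0914 in LHCN-M2. These values show no sign of pairing by number, but they cannot settle whether such libraries share a culture or day. Depth limits genes under about 3 counts per group, for which bounds are given in place of fold changes.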

Other observations

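The genes of this part, those that changed and then moved the other way and those that moved in opposite directions in the lines, were chosen after their values were seen.

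Some genes, called transient here, changed at day 1 and moved the other way by the last day. A return to the day 0 level was not required, and Car12, Chrdl1 and Vldlr ended above it. In C2C12, 187 genes rose and then fell by at least 2-fold at each step, and 174 fell and then rose. The carbonic anhydrase gene Car12 stood at 10.3 ± 2.01, 1.27 ± 0.503 and 33.3 ± 2.31 CPM at days 0, 1 and 6. Chrdl1, a BMP antagonist, stood at 1.56 ± 0.363, 0.270 ± 0.104 and 32.9 ± 2.701 CPM, and Vldlr, a lipoprotein receptor, at 0.795 ± 0.186, 0.154 ± 0.121 and 58.9 ± 2.95 CPM. The orphan receptor gene Gpr153 rose and fell (11.2 ± 0.245, 50.6 ± 2.19 and 9.89 ± 1.22 CPM), as did Aldh3a1, an aldehyde dehydrogenase (21.6 ± 1.95, 68.9 ± 6.92 and 20.5 ± 2.201 CPM).
LHCN-M2 had 299 genes that rose and then fell and 206 that fell and then rose. The peptidase gene DPP4 stood at 36.7 ± 3.12, 386 ± 7.89 and 67.1 ± 1.28 CPM at days 0, 1 and 12. SCD, which makes monounsaturated fatty acids, stood at 308 ± 50.1, 4009.8 ± 223 and 964 ± 92.1 CPM, and INSIG1, a regulator of sterol synthesis, at 169 ± 9.52, 906 ± 33.7 and 214 ± 4.15 CPM. CTGF, a matricellular protein gene, fell and then rose (366 ± 11.99, 62.4 ± 4.35 and 498 ± 23.5 CPM), as did the collagen gene COL6A3 (88.9 ± 21.8, 19.1 ± 1.39 and 95.7 ± 11.95 CPM). Both steps use the day 1 libraries. Independent calls would give 90.8 genes that rose and then fell and 71.2 that fell and then rose in C2C12, and 96.7 and 109.8 in LHCN-M2, and simulations of unchanged groups, which hold no effects, gave 0. With the day 1 libraries split between the steps, the counts were 140 and 108 in C2C12 (66.7 and 63.4 if independent) and 241 and 166 in LHCN-M2 (65.6 and 101.3).

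Other genes moved in opposite directions in the lines. At day 1, COL14A1 had a log2 fold change of -2.59 in C2C12 and 5.79 in LHCN-M2, SFRP4, a secreted Wnt antagonist, -2.14 and 3.61, and the chemokine CXCL12 -1.99 and 2.23. SEMA7A, a membrane-anchored semaphorin, went the other way (2.13 and -1.86).
At the last day, RASSF2 had -3.88 in C2C12 and 6.60 in LHCN-M2, the actin-binding LMOD1 -3.98 and 3.56, and the laminin chain LAMA4 -3.53 and 3.38. The integrin ITGA10 (3.31 and -2.95) and SEMA7A (2.88 and -2.83) rose in C2C12 and fell in LHCN-M2.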
